A study of Mus musculus with 6 samples.

How the data were processed

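Hypothalami of C57/Bl6 mice with the Klb-Cre and Ai14 alleles were pooled by 3 for each of 3 captures, digested with pronase at 2 mg/ml for 30 min at 37 °C, strained at 70 µm and sorted through a 130 µm nozzle for tdTomato and Hoechst viability, per the labels' protocols. Libraries were made with 2 custom primer panels on each capture, per the labels' protocols. The deposited values are UMI counts per cell and amplicon, with no normalization. They were made with the BD Targeted Rhapsody Analysis Pipeline, version 1.3 for panel 1 of replicate 1 and version 1.5 for the other tables, per the file headers. The counts were corrected for errors in the molecular identifiers by recursive substitution error correction, per the names of the deposited tables. The genome build was mm9, per the submitters' processing notes. The aligner, the rule for calling cells and the way panels were merged are not given in the sources used here. Gene names are those of the tables. All 328 symbols were found as a symbol or synonym in a reference table of assembly GRCm38.p6, from which no coordinates were used.

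The 6 deposited tables were checked before use. The larger set had 290 amplicons for 265 symbols, with Mbp in addition in panel 2 of replicate 3, and the smaller set had 80 amplicons for 75 symbols. Panel 1 of replicate 1 held counts in the larger set alone. The table of panel 2 of replicate 2 held 43 barcodes of its own, 25 that were identical to panel 1 of that replicate, and 21 that were also in the table of panel 1 of replicate 3. The tables of both panels of replicate 3 held the same 87 barcodes of the larger set and the same 104 of the smaller set, which in the panel 1 table stood under names of the larger set. The barcodes of panel 1 of replicate 1 kept the panel of their label. Other barcodes were assigned to the panel whose gene set they carried, under the header in which the set was placed by its own table. The 21 barcodes found in tables of 2 replicates were left out of all comparisons. Mean profiles of libraries correlated by gene name with Pearson r across amplicons from 0.479 to 0.850 in the larger set and 0.853 in the smaller. With columns moved by up to 5 places the highest were 0.120 and 0.0181. Amplicons are not independent replicates. The panels of 1 capture shared 0, 0 and 2 cell indices in replicates 1, 2 and 3, so cells were not joined across panels. The pairing of the panels by capture was used only in the fit with a replicate block and in the paired sign-flip test.

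Amplicons of 1 gene were summed. Barcodes with at least 20 UMIs and at least 5 detected genes were kept as cells, which left out 605 of 1555 barcodes of panel 1 of replicate 1 and none elsewhere. No doublets were called. Instead, the 5% of cells with the most UMIs were removed as an alternative. A gene was detected in a cell with at least 1 UMI. Shares were given with exact Clopper-Pearson 95% intervals, and a share of 0 with a limit of 3 counts of the total. Shares were repeated on cells thinned at random to 35 UMIs. Cells were not treated as replicates, and means and SD are over captures. The depth of the kept cells was 105772, 11423, 25964, 79560, 76898 and 109452 UMIs, listed by replicate with panel 1 first.

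Glutamatergic cells had a UMI of Slc17a6, Slc17a7 or Slc17a8 and none of Slc32a1, Gad1 or Gad2, and GABAergic cells the reverse, as far as each set measured them. The difference of the shares was tested with an exact two-sided sign-flip test over captures. Log counts scaled to the median total were clustered with the Leiden method on 15 neighbours, at most 20 principal components and resolution 1, with seed 0, using igraph 0.11.9, leidenalg 0.10.2 and scikit-learn 1.9.0. A cluster was to be named only with at least 3 markers of 1 list raised at least 2-fold, with 0.1 UMIs per 1000 added before each fold. Counts of shared genes summed per library were compared between the panels with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg) and DESeq2 1.42.0 in R 4.3.3. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The spread of cells around the mean profile of their library was measured by chi-square per degree of freedom over genes with at least 1 expected UMI.

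The rule for named genes was set before the data were examined, as were the comparisons, the gene lists and most of the other settings tried. It names Klb, the Fgfr genes and the 6 transmitter markers where measured, the 10 genes in the largest mean share of cells of each panel, and of each of 30 gene lists the 4 measured members with the highest mean share. No member of the cholinergic and serotonergic lists was measured. Results that rest on certain genes, among them the share of the oligodendrocyte list in the larger set, are not reported here. TdTomato, genes leading a cluster, and genes at 0 in 1 library but in nearly all cells of another were chosen after their values were seen. The other settings were a minimum of 100 UMIs, no filter on cells, thinning, detection at 2 UMIs, cells pooled over captures, only cells with a neuronal marker, other cluster resolutions, no TMM, DESeq2, no filter on low counts, a replicate block, and leaving out each replicate in turn. Clustering each library alone, and the panel fits that combine a setting with no filter on low counts, were added after the data had been seen.

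The planned gene tests between transmitter classes and between cells with and without Klb could not be run, since both classes occurred together in 1 library and no cell had a Klb UMI. The clustering, the correlation of gene pairs and the panel fits were tested on simulated data. Simulated groups differing 4-fold in part of the detected genes were recovered with 96% to 100% of cells in a cluster of their group, over the 6 libraries and 14 to 157 genes.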

Results

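UMIs, the molecules counted per cell, were measured in single cells of mouse hypothalamus with targeted BD Rhapsody primer panels. The cells came from Klb-Cre mice carrying the Ai14 reporter and were sorted for tdTomato and viability. Klb encodes the co-receptor of the hormone FGF21, and in this cross tdTomato marks cells whose lineage has expressed it. There were 3 captures, each from 3 pooled hypothalami, and 2 primer panels on each capture, which makes 6 libraries. The capture is the replicate, so panel 2 has n = 3. The libraries of panel 2 measured a larger set of 265 genes, and those labelled panel 1 of replicates 2 and 3 measured a smaller set of 75 genes. The library labelled panel 1 of replicate 1 holds counts in the larger set alone, so its shares are given apart from both and the smaller set has n = 2. It counts as panel 1, by its label, in the 3 means over all libraries of that label and in the tests on them. The same holds in the fits and splits between the panels and in the other settings tried for these.

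Of 1858 barcodes, 1253 were kept as cells, with at least 20 UMIs and at least 5 detected genes. In the order panel 1, then panel 2, replicate 1 kept 950 and 44 cells, replicate 2 kept 25 and 43, and replicate 3 kept 104 and 87. The kept cells of a library held between 11423 UMIs (panel 2 of replicate 1) and 109452 UMIs (panel 2 of replicate 3). The median cell of replicate 1 carried 51 UMIs in panel 1 and 115.5 in panel 2. In replicate 2 these medians were 1044 and 1352, and in replicate 3 they were 705 and 1068. The libraries of the larger set detected 157, 50, 93 and 120 genes in panel 1 of replicate 1 and in panel 2 of replicates 1, 2 and 3. The smaller set detected 14 genes in replicate 2 and 27 in replicate 3. All intervals are exact Clopper-Pearson 95% intervals and cover counting error alone, as do the limits for a count of 0, which bound cells with a UMI and not cells that express a gene.

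**Figure D1:**
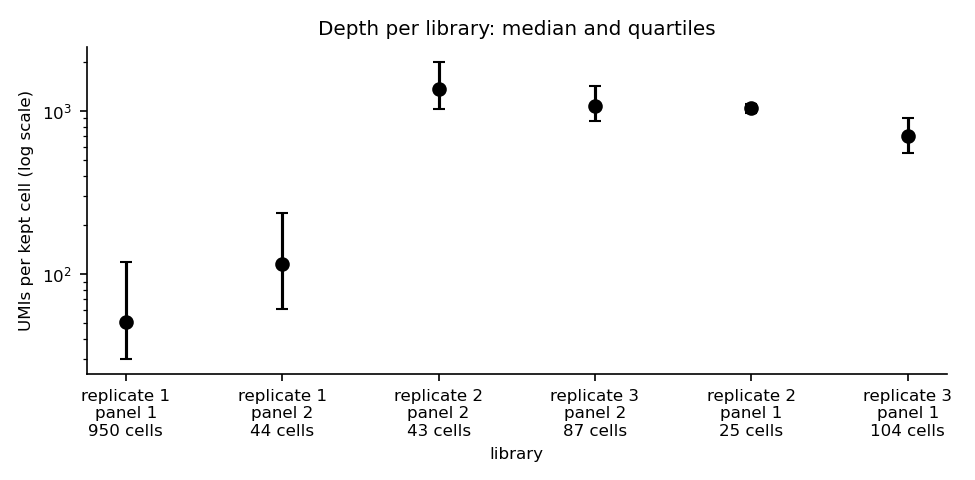
UMIs per kept cell on a log scale for each library, with points at the median and bars at the quartiles. Both libraries of replicate 1 lie below the other 4, with medians of 51 and 115.5 UMIs against 705 to 1352.

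The first comparison asks which sorted cells carried RNA of the FGF21 receptor. No cell of any library had a Klb UMI, while its partner Fgfr1 was in most cells of some libraries and in none of another. The reporter was in nearly all cells of panel 2 of replicates 2 and 3 and in no cell of panel 2 of replicate 1. Fgfr2 was in every cell of panel 2 of replicate 2 and nearly absent elsewhere. Klb (NM_031180.2) was at 0 in 1124 kept cells of the 4 libraries that measured it, which allows a share of up to 0.267%. Over all 1729 barcodes of these libraries it was also at 0, which allows up to 0.174%. By library the limits were 0.316% in panel 1 of replicate 1 and 6.82%, 6.98% and 3.45% in panel 2 of replicates 1, 2 and 3. The Klb-Cre cross records past expression, so a Klb count of 0 does not go against the labels.

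TdTomato UMIs were in 281 of 950 cells (29.6%, 26.7 to 32.6) of panel 1 of replicate 1. In panel 2 they were in 0 of 44 cells of replicate 1, which allows up to 6.82%, in 41 of 43 cells of replicate 2 (95.3%, 84.2 to 99.4) and in 86 of 87 cells of replicate 3 (98.9%, 93.8 to 99.97). Thinned to 35 UMIs a cell, the shares were 14.3% in panel 1 of replicate 1 and 0%, 9.30% and 17.2% in panel 2 of replicates 1, 2 and 3. Thinning left out 306 cells of panel 1 and 1 cell of panel 2 of replicate 1. The library labelled panel 2 of replicate 1 thus held no reporter UMI although its median depth was above that of panel 1 of the same capture.

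Fgfr1 (NM_010206.3), the receptor that FGF21 uses with Klb, was in 44.1% of cells (40.9 to 47.3) of panel 1 of replicate 1. In panel 2 it was in 97.7% of cells of replicate 1 (88.0 to 99.9), in 0 of 43 of replicate 2, which allows up to 6.98%, and in 79.3% of replicate 3 (69.3 to 87.3). The mean over panel 2 was 59% ± 51.9 (SD, n = 3). Thinned to 35 UMIs, Fgfr1 was in 25.3% of cells of panel 1 of replicate 1 and in 46.5%, 0% and 8.05% of panel 2 of replicates 1, 2 and 3. Fgfr2 (NM_010207.2), a related receptor, was in 3.89% of cells (2.76 to 5.33) of panel 1 of replicate 1. In panel 2 it was in 0 of 44 cells of replicate 1, 43 of 43 of replicate 2 and 1 of 87 of replicate 3, a mean of 33.7% ± 57.4 (SD, n = 3). The FGF21 receptor list, of which Klb, Fgfr1 and Fgfr2 were measured, was in 92.3% ± 11.3 of panel 2 cells (SD, n = 3). Within panel 2 of replicate 3 the share of Fgfr1 was 87.9% in a cluster led by the oligodendrocyte genes Ugt8a, Ermn and Mbp (median 1311 UMIs). It was 76.5% and 70.0% in the other clusters (median 1080 and 1002 UMIs), so Fgfr1 marked no cluster there.

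**Figure D2:**
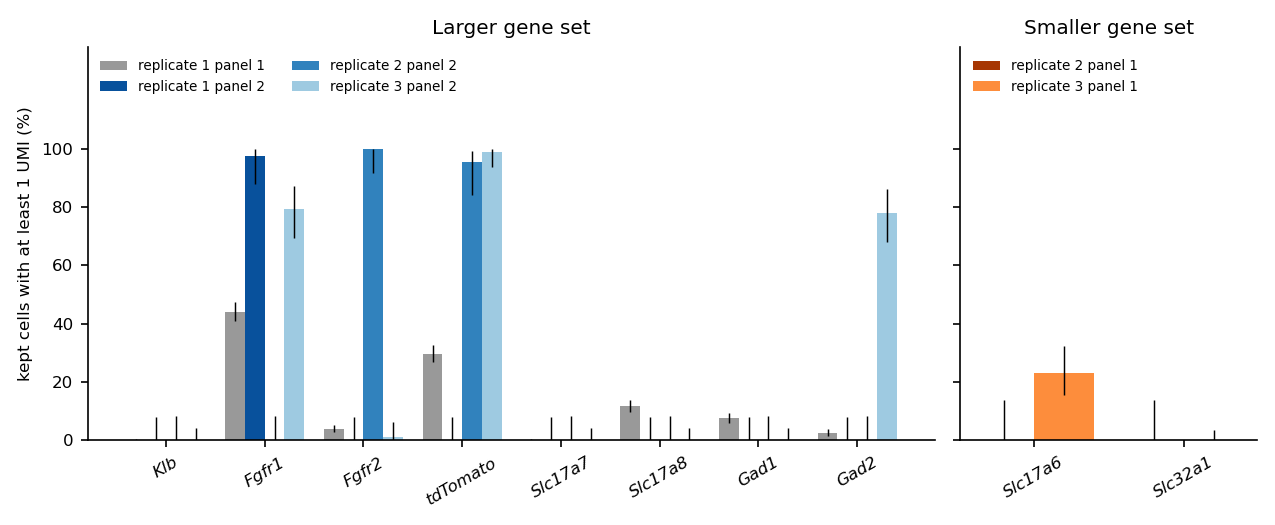
Share of kept cells with at least 1 UMI (bars, percent) for the named genes in each library, with exact 95% intervals as lines, for the larger set on the left and the smaller set on the right. Klb stands at 0 in all 4 libraries that measured it, and Fgfr1, Fgfr2, tdTomato and Gad2 reach 78.2% or more in some libraries of panel 2 and 0 in others.

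The next comparison asks whether the sorted cells were glutamatergic or GABAergic neurons. Most cells carried no transmitter marker, and no marker was found in more than 2 libraries. Slc17a6 and Slc17a8 are vesicular glutamate transporters, Gad1 and Gad2 make GABA, and Slc32a1 loads it into vesicles. The larger set measured Slc17a7, Slc17a8, Gad1 and Gad2, and the smaller set measured Slc17a6 and Slc32a1. Slc17a6 (NM_080853.3) was in 0 of 25 cells of panel 1 of replicate 2, which allows up to 12%, and in 24 of 104 cells of replicate 3 (23.1%, 15.4 to 32.4; 0.962% thinned). Slc32a1 was in no cell of these 2 libraries, which in replicate 3 allows up to 2.88%. Slc17a7 was at 0 in all 4 libraries that measured it. Slc17a8 (NM_182959.3) was in 111 of 950 cells (11.7%, 9.71 to 13.9; 4.97% thinned) and Gad1 (NM_008077.5) in 72 (7.58%, 5.98 to 9.45; 2.48% thinned) of panel 1 of replicate 1, and both were at 0 in panel 2. Gad2 (NM_008078.2) was in 2.53% of cells (1.63 to 3.74) of panel 1 of replicate 1, in none of panel 2 of replicates 1 and 2, and in 68 of 87 cells (78.2%, 68 to 86.3; 2.30% thinned) of replicate 3.

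Transmitter markers were also counted within clusters, but simulated cells of 1 profile gave at least as many clusters in every library, so no cluster served as a background without the marker. Within panel 2 of replicate 3, Gad2 was in 29 of 33 cells (87.9%, 71.8 to 96.6) of the cluster led by Ugt8a, Ermn and Mbp. It was in 70.6% (52.5 to 84.9) and 75% (50.9 to 91.3) of the others. In panel 1 of replicate 1, the cluster led by the vessel transporters Slco1a4, Slco1c1 and Slc2a1 (23 cells, median 182 UMIs) had Slc17a8 in 21.7% (7.46 to 43.7) and Gad1 in 17.4% of cells. Per 1000 UMIs it had 0.491 of Slc17a8, against 3.17 in cluster 1, which was led by Nme5 (median 72 UMIs).

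Cells were classed by markers of 1 class and none of the other. In panel 1 of replicate 1 the glutamatergic class rested on Slc17a8 alone, since Slc17a7 was at 0 and Slc17a6 was not measured. That library had 90 glutamatergic cells (9.47%, 7.69 to 11.5) and 69 GABAergic cells (7.26%, 5.69 to 9.10). A further 21 cells (2.21%) carried both and 770 (81.1%) neither. The median depth was 128.5, 117, 331 and 45 UMIs in these classes. Bcas1, an oligodendrocyte gene, was in 97.8% of the glutamatergic, 98.6% of the GABAergic and 96.0% of the other cells. Stmn2, a neuronal cytoskeleton gene, was in 12.2%, 11.6% and 8.31%. The share of glutamatergic minus GABAergic cells was 11.5 points ± 16.3 in the smaller set (SD, n = 2). Over all 3 libraries labelled panel 1, of which replicate 1 was classed on the markers of the larger set, it was 8.43 points ± 12.7 (SD, n = 3), higher in 2 of 3 captures, with an exact two-sided sign-flip p of 0.5, and 1.11 points without replicate 3. In panel 2 it was -26.1 points ± 45.1 (SD, n = 3; exact p of 1), which rests on Gad2 in replicate 3 alone and is 0 without that capture. With 3 captures the smallest p this test can give is 0.25, and only where no capture has a difference of 0. Replicate 2 was at 0 in panel 1, and replicates 1 and 2 were at 0 in panel 2. Both p were therefore the smallest possible with these captures, and neither test could have found a difference. Both classes were present together in only 1 library, and no cell had a Klb UMI. In replicate 3 the glutamatergic cells were in panel 1 and the GABAergic cells in panel 2, which measured different markers. Gene tests between the classes, and between cells with and without Klb, could therefore not be run.

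The genes found in most cells came from several cell types at once. In panel 2, 9 genes were in every cell of all 3 captures. They were Fcer1g, an Fc receptor subunit of myeloid cells, the mitochondrial carrier Ucp2, the corepressor Trim28, Grina, the early response gene Btg2, the splicing factor Sf1, Bcas1, the clock repressor Bhlhe41 and Atad1. Acta2, smooth muscle actin, followed in 99.6% ± 0.664 of cells (SD, n = 3). Fcer1g had the most UMIs, 31.3, 154 and 124 a cell in replicates 1, 2 and 3, or 12.1%, 8.35% and 9.88% of all UMIs. In the smaller set the complement gene C1qa took 85.0% of the UMIs of replicate 2 and 92.7% of those of replicate 3. C1qa, the microglial chemokine receptor Cx3cr1 and the myelin gene Mag were in every cell of both captures. Mt1 was in 99% ± 1.36, Pdgfra in 97.1% ± 4.08, Rarres2 in 95.7% ± 6.12 and the macrophage receptor Mrc1 in 87.2% ± 4.51 of cells (SD, n = 2). The next 3 genes differed between the captures. Pvalb was in 100% of cells of replicate 2 and 2.88% of replicate 3, Snap25 in 12% and 76.9%, and Rax in 0% and 85.6%. In panel 1 of replicate 1 the 10 most widespread genes ran from Bcas1 (96.4%), the precursor gene Cspg4 (90.9%) and Fn1 (90.2%) through Mt2, Rarres2, Slco1c1, Anxa2, Trim28 and Ucp2 to Btg2 (79.6%).

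A sort for a reporter can also hold glia, tanycytes, vessel and immune cells, so markers of these types were counted in every library. Markers of several types shared the same cells at full depth, and fewer types were seen in a cell at equal depth. The mean cell carried UMIs of 5.47 ± 1.11 of the cell type lists in panel 2 (SD, n = 3) and of 4.97 ± 0.756 in the 3 libraries labelled panel 1, which measured different sets (SD, n = 3). Thinned to 35 UMIs, it carried 3.51, 0.558 and 1.90 lists in panel 2 of replicates 1, 2 and 3, and 4.09, 2.52 and 1.94 in panel 1. Cells with at least 2 UMIs of each of at least 3 lists made up 56.7% of panel 1 of replicate 1 and between 79.5% and 100% of the other libraries. Microglial genes were measured in the smaller set alone and took 883 and 953 of each 1000 UMIs in replicates 2 and 3, with Aif1 in 64% and 3.85% of cells.

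At full depth, markers of precursors and ependymal cells were in most cells of every library, and mural genes in most cells of panel 2, but at equal depth this did not hold. Astrocyte, tanycyte, neuronal, endothelial and fibroblast genes differed between libraries, also between both libraries of replicate 1. Tanycyte genes were in 80.6% of its panel 1 cells and 0% of its panel 2 cells, and astrocyte genes in 66.1% and 97.7%. Precursor genes were in 99.2% ± 1.31 of panel 2 cells (SD, n = 3) and 97.6% ± 3.40 of the smaller set (SD, n = 2), by Cspg4, Fyn, Pdgfra and Olig1. Ependymal genes were in 96.9% ± 3.56 and 96.6% ± 4.76 of cells, by Rarres2, with Foxj1 in 12.5% of panel 1 of replicate 3 and Ccdc153 and Tmem212 at 0. Oligodendrocyte genes were in 100% of cells of the smaller set, by Mag, with Mobp in 0% and 62.5% and Olig1 in 4% and 57.7%. Astrocyte genes were in 72.5% ± 35 of panel 2 cells and 2.88% ± 4.08 of the smaller set. The gap junction gene Gja1 was in 97.7%, 0% and 19.5% of panel 2 cells of replicates 1, 2 and 3, the filament gene Gfap in 0%, 32.6% and 85.1%, Sox9 in 5.77% of panel 1 of replicate 3 and Agt in none. Tanycyte genes were in 48.9% ± 46.7 and 42.8% ± 60.5, with Nes in 0%, 51.2% and 55.2%, Vim in 0%, 0% and 87.4% and Crym in 0%, 4.65% and 0% of panel 2 cells. Thinned to 35 UMIs, the shares in panel 2 of replicates 1, 2 and 3 were 69.8%, 16.3% and 42.5% for precursor genes, 81.4%, 18.6% and 23% for ependymal genes and 88.4%, 4.65% and 9.20% for mural genes.

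Neuronal genes were in 11.7% of cells of panel 1 of replicate 1, in 31.8% ± 55.1 of panel 2 cells, all by Stmn2 in 95.5% of replicate 1, and in 44.5% ± 45.9 of the smaller set, by Snap25. Syt1, a synaptic vesicle gene, was at 0 in all 6 libraries, and Tubb3 was in 2.63% of panel 1 of replicate 1 and at 0 in panel 2. Stmn2 was in at least 93.8% of each cluster of panel 2 of replicate 1, among them a cluster of 11 cells led by Gja1. Mural genes were in 99.6% ± 0.664 of panel 2 cells, by Acta2, with Mustn1 at 0, and in 50.9% of panel 1 of replicate 1. Fibroblast genes were in 38.5% of cells of panel 1 of replicate 1, with Col3a1 in 35.7% and Lum in 6.95%. In panel 2 they were in 31.8% ± 55.1, all from replicate 3, where Col3a1 was in 86.2%, Lum in 66.7% and Col1a1 in 11.5%. Endothelial genes were in 86.3% of cells of panel 1 of replicate 1, by Slco1c1, and at 0 in the other 5 libraries, Cldn5 included. Pars tuberalis genes were in 25.7% of panel 1 of replicate 1 and 53.6% ± 50.4 of panel 2 cells, with Timeless in 0%, 100% and 60.9%, the thyrotropin gene Tshb in 0%, 95.3% and 0%, against 12.1% of panel 1 of replicate 1, and Cyp2f2 at 0.

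**Figure D3:**
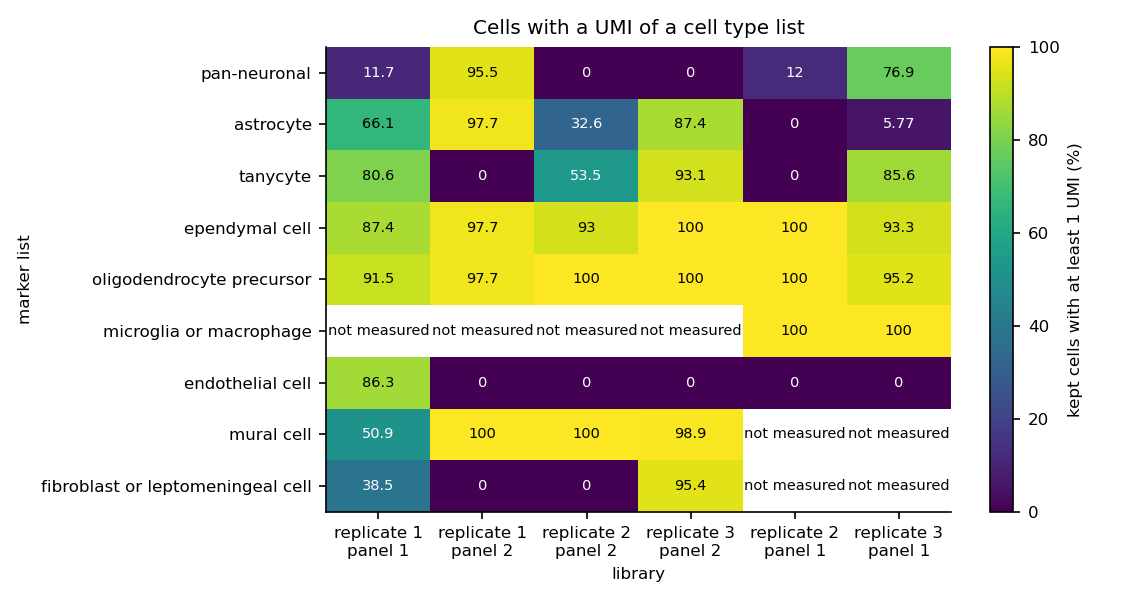
Share of kept cells (percent, colour and number) with at least 1 UMI of each of 9 marker lists (vertical) in each library (horizontal). At full depth, ependymal and precursor lists reach 87.4% or more in all 6 libraries, while the neuronal list ranges from 0 to 95.5% and the endothelial list is above 0 in panel 1 of replicate 1 alone.

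Genes that mark hypothalamic regions were counted to ask where the sorted cells lay. Several lists rested on a single gene, such as Per2 for the suprachiasmatic and Hdc for the mammillary list in panel 1 of replicate 1. The shares therefore do not locate the cells. All region lists except the lateral and paraventricular were found in all 3 captures, but panel 2 of replicate 1 held none of them. In panel 1 of replicate 1 the preoptic list rested on 1 UMI and the arcuate list on 7. In panel 1 of replicate 1 the suprachiasmatic list was in 27.3% of cells, the mammillary list in 11.8%, the ventromedial in 10.3%, the dorsomedial in 6.84%, the arcuate in 0.737% and the preoptic in 0.105%, and the lateral and paraventricular lists were at 0. In panel 2 the oestrogen receptor Esr1 gave 55.9% ± 48.6 (SD, n = 3) of cells for both the ventromedial and the preoptic list, from 0%, 88.4% and 79.3% in replicates 1, 2 and 3. These shares are at full depth. Thinned to equal depth, the ventromedial list was in 4.35% of cells of panel 1 of replicate 1. In panel 2 of replicates 1, 2 and 3 it was then in 0%, 2.33% and 6.90%. Nr5a1, a ventromedial transcription factor, was in 18.6% of panel 2 of replicate 2 and 2.11% of panel 1 of replicate 1, and Adcyap1, Bdnf and Gal were at 0 in the smaller set. The clock gene Per2 gave 39.6% ± 36.7 for the suprachiasmatic list in panel 2, with Avp, Grp and Lhx1 at 0 in the smaller set. Thinned to equal depth, this list was in 14.1% of cells of panel 1 of replicate 1. In panel 2 of replicates 1, 2 and 3 it was then in 0%, 4.65% and 4.60%. The other shares of region lists are at full depth and do not rank libraries of different depth. The arcuate list was in 43.9% ± 41.6 of panel 2 cells, by the opioid peptide gene Pdyn in 82.8% of replicate 3 and the dopamine enzyme Th in 48.8% of replicate 2. It was in 6.73% ± 9.52 of the smaller set, by Sst, with Agrp at 0. Pdyn also led the lateral hypothalamic list in panel 2 (30.7% ± 53.1). In the smaller set that list was in 53.7% ± 13.8 of cells (SD, n = 2), by the orexin gene Hcrt in 44% of replicate 2 and by Tac1 (47.1%) and Nts (39.4%) in replicate 3. The mammillary list was in 23.3% ± 40.3 of panel 2, by Hdc, and in 47.7% ± 11.7 of the smaller set, by Cck in 56% of replicate 2 and Nts in replicate 3, with Foxb1 at 0. The dorsomedial list was at 0 in panel 2, Lepr included, and in 5.44% ± 3.62 of the smaller set by Npvf. The paraventricular list was at 0 in panel 2, Mc4r included, and in 0.481% ± 0.680 of the smaller set by Trh, with Crh at 0. Tac1 gave the ventromedial list 23.6% ± 33.3 in the smaller set.

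The lists of appetite receptors, of steroid and nuclear receptors and of immediate early genes were found in all 3 captures and were at 0 in panel 2 of replicate 1, where Btg2, not on the list, was in every cell. Among appetite receptors the insulin receptor Insr was in 45.3% of panel 1 of replicate 1 and in 0%, 95.3% and 100% of panel 2 of replicates 1, 2 and 3, the stress hormone receptor Crhr1 in 2.30% of replicate 3, and Calcr and Cckar at 0. The list of these receptors was in 65.1% ± 56.4 of panel 2 cells and at 0 in the smaller set. Steroid and nuclear receptors were in 56.7% ± 49.2, by Esr1 and by Thrb in 21.8% of replicate 3, with Esr2 and Pgr at 0 in panel 2. Immediate early genes were in 84.3% of panel 1 of replicate 1, with Fos in 60.8% and Nr4a1 in 69.6%. In panel 2 they were in 66.3% ± 57.4, with Fos in 0%, 100% and 94.3%, Nr4a1 in 0%, 100% and 77%, Arc in 0%, 6.98% and 57.5% and Fosb in 0%, 0% and 10.3%. Neuropeptide genes were in 27.6% ± 47.8 of panel 2, all by Pdyn, and in 74.6% ± 7.62 of the smaller set (SD, n = 2), by Cck, Hcrt and Tac1 among others. Histaminergic genes were in 23.3% ± 40.3, by Hdc in 69.8% of replicate 2, and dopaminergic genes in 16.3% ± 28.2, by Th, with Slc6a3 and Slc18a2 at 0. GABAergic genes were in 26.1% ± 45.1 and glutamatergic genes in 0% of panel 2, against 0% and 11.5% ± 16.3 of the smaller set (SD, n = 2).

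Clusters asked which groups of cells the libraries held. Clustered together without correction between libraries, the libraries separated, from a cause that was not tested, so this does not show whether groups of cells recur. The 3 libraries of panel 2 gave 4 clusters and the smaller set 4, and each cluster held cells of 1 library. Cluster 2 of panel 2 held all 44 cells of replicate 1 and was led by Stmn2, Gja1 and the neurotrophic receptor Gfra2. Cluster 3 held all 43 cells of replicate 2 and was led by Fgfr2 and Tshb. The cells of replicate 3 divided into cluster 1, with 45 cells led by Vim and the collagen genes Col3a1 and Col9a2, and cluster 4, with 42 cells led by the thyroid hormone receptor Thrb, Adra2a and Pdyn. In the smaller set cluster 4 held the 25 cells of replicate 2, led by Pvalb and Aif1. Those of replicate 3 were led by Tac1 and Snap25 (42 cells) or Olig1 and Adcyap1r1 (30 cells), or had no gene raised more than 1.06-fold (32 cells). No cluster had 3 markers of any cell type list raised at least 2-fold, so all stay unnamed. Lists with fewer than 3 measured members could give no name. Among them were the endothelial, mural and ependymal lists in panel 2 and the neuronal, astrocyte and tanycyte lists in the smaller set.

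Within single libraries some clusters were led by related genes. A group rich in Ugt8a and Bcas1 was found in panel 2 of both replicates 2 and 3, each time with raised markers of other cell types. In panel 2 of replicate 2, 18 of 43 cells carried more UMIs per 1000 of Fgfr2 (7.65-fold) and of the myelin genes Ugt8a (6.41-fold) and Bcas1 (4.58-fold). The tanycyte gene Nes and the pars tuberalis genes Tshb and Timeless were also raised at least 2-fold in them. In panel 2 of replicate 3, 33 of 87 cells were led by Ugt8a (3.39-fold), Ermn (2.90-fold) and, among others, Mbp (2.62-fold). These cells had 22.3 Bcas1 UMIs per 1000, against 9.74 and 10.1 in the other clusters. The astrocyte gene Gfap and the fibroblast gene Col3a1 were also raised at least 2-fold in them. Folds were taken on the counts that formed the clusters, so they do not test these groups. Panel 1 of replicate 1 gave 9 clusters. Of these, 40 cells had 6.81-fold more Fcer1g (median 160 UMIs), 144 cells had 4.74-fold more Bcas1, and 23 cells had more Slco1a4 (4.39-fold), Slco1c1 (4.16-fold) and Slc2a1 (3.74-fold). Simulated cells drawn from the mean profile of each library gave 9, 3, 2, 3, 5 and 5 clusters against 9, 3, 2, 2, 4 and 3 in the data, listed by replicate with panel 1 first, so the number of clusters alone does not show cell types.

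The last comparison asks whether the panels counted their shared genes alike on the same captures. Rarres2 was the only gene that could be compared in depth, and its counts per cell overlapped between the panels, which does not show that the panels counted alike. Of 12 genes in both sets, 4 had a UMI in a kept cell and 1 passed the planned filter on low counts. The edgeR quasi-likelihood test called 0 genes past an adjusted p of 0.05 and 0 at an unadjusted p of 0.05, and DESeq2 also called 0 at both. These fits could not have called Rarres2, since libraries were scaled by the shared genes, of which Rarres2 gave nearly all UMIs, so its own difference was removed (p of 1). Rarres2 had 4.65, 12.9 and 3.63 UMIs a cell in the libraries labelled panel 1 of replicates 1, 2 and 3, the first with the larger set (mean 7.07 ± 5.09, SD, n = 3). In panel 2 it had 13.6, 6.16 and 11.7 (mean 10.5 ± 3.85, SD, n = 3). The exact two-sided permutation p was 0.3 and the smallest possible was 0.1. With the panels paired by capture, the exact two-sided sign-flip p was 0.5 and the smallest possible was 0.25. Rarres2 was higher in panel 2 in 2 of 3 captures, replicates 1 and 3. In replicate 1 both libraries held the larger set, and replicates 2 and 3, which compared the sets, went opposite ways. Klhl1, Npy1r and Oprl1 had at most 83 UMIs in any library and were at 0 in the smaller set. Simulated data with a 4-fold change in Npy1r, run on the 4 shared genes with a UMI, gave a call in 39% of 100 simulations. The library labelled panel 1 of replicate 1 measured the larger set, so it adds no measurement of the smaller panel.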

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

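Except for the tests of depth by halving the UMIs, of several cells per barcode and of amplicons that fail singly, the tests in this part were chosen only after the result was seen. The labels give no condition that differs between captures, so no biological explanation but the animals of a capture was tested.

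Klb was at 0 UMIs in all 4 libraries that measured it, although the sort was for cells of the Klb lineage. Too few UMIs stay open: halving the UMIs of a library lost at most 2.9% of its detected genes, but these had a median of 113.5 to 369 UMIs a library, so the measure is saturated and could not show a scarce transcript. Primers that gave no product stay open: 92 of the 265 genes of the larger set (34.7%), Klb among them, had no UMI in any barcode of these libraries, but 9 of the 92 had UMIs in the 21 barcodes assigned to no library, if the header chosen for these is right. Sorted cells without the reporter stay open for replicate 1, where tdTomato was in 29.6% of panel 1 cells and 0% of panel 2 cells. In panel 2 of replicates 2 and 3 it was in 95.3% and 98.9% of cells. This argues against that explanation there, as far as these UMIs came from the cells themselves. The contrast with panel 1 of replicate 1 was seen at full depth only. At equal thinned depth its share lay between those of panel 2 of replicates 2 and 3, while panel 2 of replicate 1 stayed at 0%. Past but not current Klb expression in the sorted cells was not tested and stays open.

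At full depth, most barcodes carried markers of several cell types at once. A single cell type as the only content of all barcodes stays open. The median barcode held at least 3 cell type lists with 2 or more UMIs in every library (6 in panel 2 of replicate 3). This count was made at full depth, and several lists rested on a single gene each, so it cannot decide. At equal thinned depth the mean barcode held 3.51, 0.558 and 1.90 lists in panel 2 of replicates 1, 2 and 3. In panel 1 of these replicates it held 4.09, 2.52 and 1.94. Free RNA as the whole content stays open for the barcodes of replicate 1 with 50 to 99 UMIs. Their median chi-square per degree of freedom was 0.798 in panel 1 and 0.854 in panel 2 (12 barcodes). Barcodes simulated from the library mean had a typical median of 0.966 and 0.970, and medians of up to 1.06 and 1.42. The test looked only for values above the simulated ones. The observed values lay below the typical simulated ones, so they do not show that these barcodes follow the library mean. Free RNA as the whole content is argued against for the 25% of barcodes of replicate 1 with the most UMIs (1.32 and 2.73, against simulated medians of up to 1.07 and 1.42). It is also argued against for replicate 2 and panel 2 of replicate 3 (at least 3.81 against up to 1.12, and at 100 UMIs 1.28, 2.04 and 1.73, each above its simulated medians). For panel 1 of replicate 3 it stays open. The median there was 1.32 against up to 1.03, but 0.933 against up to 0.992 when thinned to 100 UMIs. The simulated barcodes varied by counting error alone, so other noise could also raise these values. Several cells per barcode stay open, since at equal thinned depth the 25% of barcodes with the most UMIs held at most 0.636 more lists than the 25% with the fewest, and in panel 2 of replicate 1 they held fewer (-1.45).

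In panel 2, whose 3 libraries were all processed with pipeline version 1.5, 46 genes lay in at least 90% of cells of 1 library and at 0 in another, among them Fgfr1, Fgfr2, Gja1, Stmn2 and Tshb. Lower depth of the library at 0 is argued against, since 9 of them were at 0 in a library with more UMIs per barcode, and in all 73 such cases at least 27.6 UMIs would follow from the gene's share of UMIs in the other library (1692 for Fgfr1 in replicate 2). Different animals stay open: for 27 of the 38 genes at 0 in panel 2 of replicate 1, the library labelled panel 1 of that capture held a share from which at least 10 UMIs would follow (263 for Nr4a1), but it held another gene set than its label, was processed with pipeline version 1.3 and shared 0 cell indices with panel 2, so that both are of 1 capture rests on the label. Priming that failed for single amplicons stays open, since in 71.4% of 14 genes with several amplicons all amplicons were detected or at 0 together, but Stmn2, Gria2 and Vipr1 each had 1 amplicon at 0 in all 3 libraries, and of the 8 genes whose amplicons all worked somewhere and switched, 7 switched together and Tmem18 did not.

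The 21 barcodes found in the tables of 2 replicates were used in no comparison and carried signal above the limit that a count of 0 allows. Their values followed panel 2 of replicate 3 under the header with Mbp (Pearson r 0.558 across 143 amplicons) and not under the header they were placed in (-0.0271), so they are given under the first, which is not certain: under it Pigv, Pou2f2, Ninl and Glipr1, in 100% of cells of panel 2 of replicate 3, were at 0, while Htr2c, at 0 in all 4 libraries that measured it, was in 85.7%. Mbp and tdTomato were in 100% of them, Stmn2 in 85.7%, Gad1 and Fgfr2 in 81% each, Fgfr1 in 71.4%, Tubb3 in 66.7%, Gad2 in 61.9% and Syt1, at 0 in all 6 libraries, in 33.3%. Of their 23969 UMIs, 1 barcode held 16922. The median barcode had 73 UMIs of Mbp and 2 of Stmn2, but only 1 each of tdTomato, Gad1, Gad2, Fgfr1, Fgfr2 and Tubb3. Klb was at 0 here too. Mbp, which panel 2 of replicate 3 alone measured, was in 100% of its kept cells. Among the 605 barcodes left out of panel 1 of replicate 1 for low counts, Bcas1 was in 66.8%.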

How the results depend on the processing

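The clustering of each library alone and the panel fits that combine a setting with no filter on low counts were tests chosen only after the result was seen. Klb stayed at 0 in every setting. The share of glutamatergic minus GABAergic cells was above 0 in panel 1 in every setting (0.890 thinned to 12.6 without replicate 2), and in panel 2 it was -50 to 0, being 0 without replicate 3 and -0.766 thinned. The number of clusters depended on resolution: at 0.5 and 2 the smaller set gave 2 and 13 clusters and panel 1 of replicate 1 gave 4 and 24, while panel 2 gave 3 and 6. Leaving out each replicate gave 2 to 3 clusters in panel 2 and 2 to 4 in the smaller set, in each case the fewest without replicate 3. Replicate 3 had formed clusters 1 and 4 of panel 2 and clusters 1, 2 and 3 of the smaller set. Each other library had formed a cluster of its own, so leaving out replicate 3 took away the most clusters. Clustering each library alone gave 8 in panel 2. Cell type lists per cell in panel 1 fell to 3.93 when 2 UMIs were required, since fewer lists pass in a cell. Between the panels, edgeR and DESeq2 called 0 genes in all fits, 0 also at an unadjusted p of 0.05, and 0 with the replicate block that pairs the panels of a capture, but all fits were scaled by the shared genes, nearly all Rarres2, so they do not show that the panels counted alike. Without the filter the smallest adjusted p ranged from 0.404 to 0.983. All 10 splits of the 6 libraries into 3 and 3 gave at least the 0 genes of the real one, the highest other gave 1, and 10 splits are too few for a share under 0.05. Counting each result under each setting, 70 values of the main results counted as stayed and 8 as moved, 7 numbers of clusters and the lists per cell given above. Shares stayed if within the spread, and numbers of clusters or genes if within 1.5 times the count. Tested differences stayed if their p kept its side of 0.05 and their sign was not reversed. Of single genes and lists 139 values stayed and 5 moved, of the ependymal, precursor and mural lists. This tally does not show stability. Klb had no UMI in any barcode, so it could only stay, and the transmitter p could not fall under 0.05 in any setting. The panel fits were limited by their scaling, as given above. The spread was also wide. Fgfr2 in panel 2 counts as stayed at 0.575% without replicate 2, against 33.7%, and Gad2 at 0 without replicate 3, against 26.1%. Gene tests between transmitter classes and by Klb, and panels joined by cell index, were not run. Depth limits replicate 1: at 35 UMIs a cell tdTomato was in 9.30% of panel 2 cells of replicate 2, against 95.3% at full depth.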

Other observations

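The test of gene pairs in this part was chosen only after the result was seen. If the captures shared cell types, the same genes could vary together between cells in separate libraries. Pearson r of gene-pair correlations between libraries of the larger set ran from 0.0442 to 0.377 and exceeded the highest of 1000 shuffles in 3 of 6 pairs of libraries, so shared groups of genes stay open. Cspg4 and Rarres2 were among the leading gene pairs in 4 of the 6, and Bcas1 with Ugt8a, both myelin genes, led between panel 2 of replicates 2 and 3. Gene pairs are not independent replicates. On simulated data the same r was 0.562 to 0.870 for libraries that share groups and -0.144 to 0.0149 for libraries of 1 profile each.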
